A study of Mus musculus with 21 samples.

How the data were processed

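RNA from mouse colon and ileum was sequenced from poly(A)-selected libraries, per the labels' protocols, in 21 samples. The labels place each sample in 1 of 6 groups, made of a tissue and 1 of KO, uninjected transgenic or treated transgenic. They give no identifier of an animal, so the p-values measure only the spread between these samples. The design text of the series counts 3 uninjected and 4 treated colon samples, whereas the labels and columns give 4 and 3, which were followed. All choices of test, gene lists, alternatives and named genes were made before the data were examined, except where a choice is said to have come later.

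The deposited values are FPKM per gene in 6 tables of 21441 genes, each holding 2 groups of 1 tissue. Mapping was done with CLC Genomics Workbench, per the labels' protocols, and the submitters' processing notes also name mm9, kallisto 0.45.0, DESeq 1.14.0 and DESeq2, with no role for each. The annotation and filters used upstream are not given in the sources used here. A total of 25 gene symbols are written as dates in the deposited tables and were left as they stand. The same library differed between the tables of its tissue by 1 constant factor for all genes, between 0.9328 and 1.0721 in the colon and between 0.9151 and 1.0928 in the ileum. Each table was therefore scaled over its own libraries, and the main tests between groups were made only within a table. Exceptions among the alternatives were the fits of 3 groups at once, which joined libraries of 2 tables after rescaling, and voom on reads recovered over joined tables. Columns of the treated groups and of the uninjected ileum group carry a number that ties them to their group but not to a single sample, so they were used as replicates of the group without a sex or age of their own. They are named here by the column's number.

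Low FPKM values of a gene were whole multiples of a step, from which reads were recovered. With a tolerance of 0.01, 82.69% of 18779 genes above 0 in the colon and 82.38% of 18255 in the ileum came out as whole reads in the libraries of their tissue; a further 3200 and 3172 genes were taken as approximate and 50 and 44 were left out. The depths so estimated are not totals given by the submitters. Read counts served for the depth and for 1 alternative, limma's voom, and never for the main test.

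For each pair of groups, log2(FPKM + 0.5) of genes with a mean of at least 1 FPKM over the libraries of the fit was tested by limma 3.58.1 with an intensity trend in the prior, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes and log2 differences are on this log2(FPKM + 0.5) scale, which understates changes of low genes. The difference of an effect between tissues was tested in 1 limma fit over both tissues, as the ileum effect minus the colon effect. For the genes of the protocol's qPCR panel and for Vdr, an exact two-sided permutation test of the mean FPKM was added. Means are given ± SD. Fits used R 4.3.3, tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. Gene coordinates are those of the mm9 annotation, matched by symbol.

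A total of 32 gene lists with 452 entries, covering pathways and cell types of the intestine, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Of these entries 433 were found in the tables, 9 of them by an older symbol, and a list of mitochondrially encoded genes had no member there. Named genes are the qPCR panel and Vdr, up to 10 genes in each direction with the largest changes among those past the threshold whose groups did not overlap and whose higher group had a mean of at least 2 FPKM, and up to 4 members of each list with the smallest p. For the difference between tissues, the panel and up to 5 genes in each direction could be named, and sex-linked genes only as a check of the labels. A gene that met the rule is not reported here, though it stays in the counts.

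The fits were tested on simulated libraries with 200 changed genes over 10 draws. In treated minus KO colon, the limma fit recovered 1% of 1.5-fold, 12.6% of 2-fold, 72% of 4-fold and 88.6% of 8-fold changes; in uninjected minus KO colon it recovered 65% of 4-fold changes, in the same comparison of the ileum 45.6% and in treated minus KO ileum 44%. False calls had medians of 0 to 0.5 per draw, but single draws held up to 12 in uninjected minus KO colon, 11 in treated minus uninjected colon, 6 in treated minus KO colon, and 8, 0 and 5 in the same comparisons of the ileum in that order. The test of the tissue difference recovered 33.2% of 4-fold changes for uninjected minus KO and 35.2% for treated minus KO, with up to 2 and 6 false calls in a draw. In these draws camera at the preset correlation also called a median of 2 to 8 lists that held no change, and with an estimated correlation a median of 0, at which a raised list was called in 0 to 7 of 10 draws.

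Libraries with the same number in treated and KO ileum deviated together from their group means in each of 3 pairs (correlations across genes between 0.113 and 0.505), so for that comparison the number was also used as a block. The labels do not say what the numbers mark. Alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, 3 groups in 1 fit, the labelled sex as a covariate, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were the removal of each library's trend on transcript GC content and length, voom on recovered reads, and fits without pairs of libraries that stood apart. Library weights estimated by limma were tried after seeing the data and left out, since on simulated libraries of the treated and uninjected ileum they called a median of 7266 unchanged genes.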

Results

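RNA was measured in the intestine of mice that differ in the vitamin D receptor (VDR), the nuclear receptor for 1,25-dihydroxyvitamin D3 (1,25D3). Per its title, the series asks what the distal segments of the intestine contribute to calcium balance and to the mineral content of bone. The KO animals had lost VDR from the intestinal epithelium by a tamoxifen-inducible Cre recombinase driven by the villin promoter. The transgenic animals lacked their own VDR and carried human VDR under a CDX2 promoter, which places it in the distal intestine. They were studied uninjected or treated with 3 injections of 1,25D3 (1 ng per g of body weight), given 48, 24 and 6 h before the end of the experiment. KO and transgenic mice thus differ in how and where their own VDR was lost, as well as in the transgene. Tamoxifen, if only the KO mice received it, would coincide with these differences too. Treated mice are set against uninjected ones, so that injection itself coincides with 1,25D3. These cannot be told apart here. Colon was sampled in 4 KO, 4 uninjected and 3 treated samples, and ileum in 4 KO, 3 uninjected and 3 treated samples, 21 libraries in all. By the labels, KO and treated mice were male and 5 of the 7 uninjected samples female, so that sex and group partly coincide. Y-linked Ddx3y, however, stood at 2.32 to 15.0 FPKM in 4 of the 7 uninjected libraries and at most at 0.21 in the others. In each tissue 3 of the 4 KO samples came from mice aged 11 weeks and 1 from a mouse aged 9 weeks. Treated mice were 9 weeks old and uninjected mice 9 or 10, so age and group partly coincide as well. Reads recovered from the steps of the FPKM values put the depth of the colon libraries between 10.68 and 42.81 M reads and that of the ileum libraries between 15.0 and 47.14 M. Between 15548 and 17110 genes were above 0 in each of the 21 libraries.

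The targeted gene, mouse Vdr (15:97684856-97741061, mm9), was read in each of the 21 libraries. In the colon its level was 22.9, 23.5, 20.6 and 20.9 FPKM in the KO libraries, 34.0, 19.3, 12.7 and 33.0 in the uninjected libraries and 39.9, 20.7 and 31.9 in the treated libraries. In the ileum it was 20.1, 20.6, 19.3 and 21.0 FPKM in KO, 23.3, 22.1 and 24.9 in uninjected and 13.4, 18.5 and 22.6 in treated libraries. A value per gene does not resolve the deleted part of Vdr, and reads of the human transgene can fall on the mouse gene, so these levels do not check the labels. None of the 6 comparisons called Vdr (adjusted p between 0.698 and 1.0, limma).

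**Figure D1:**
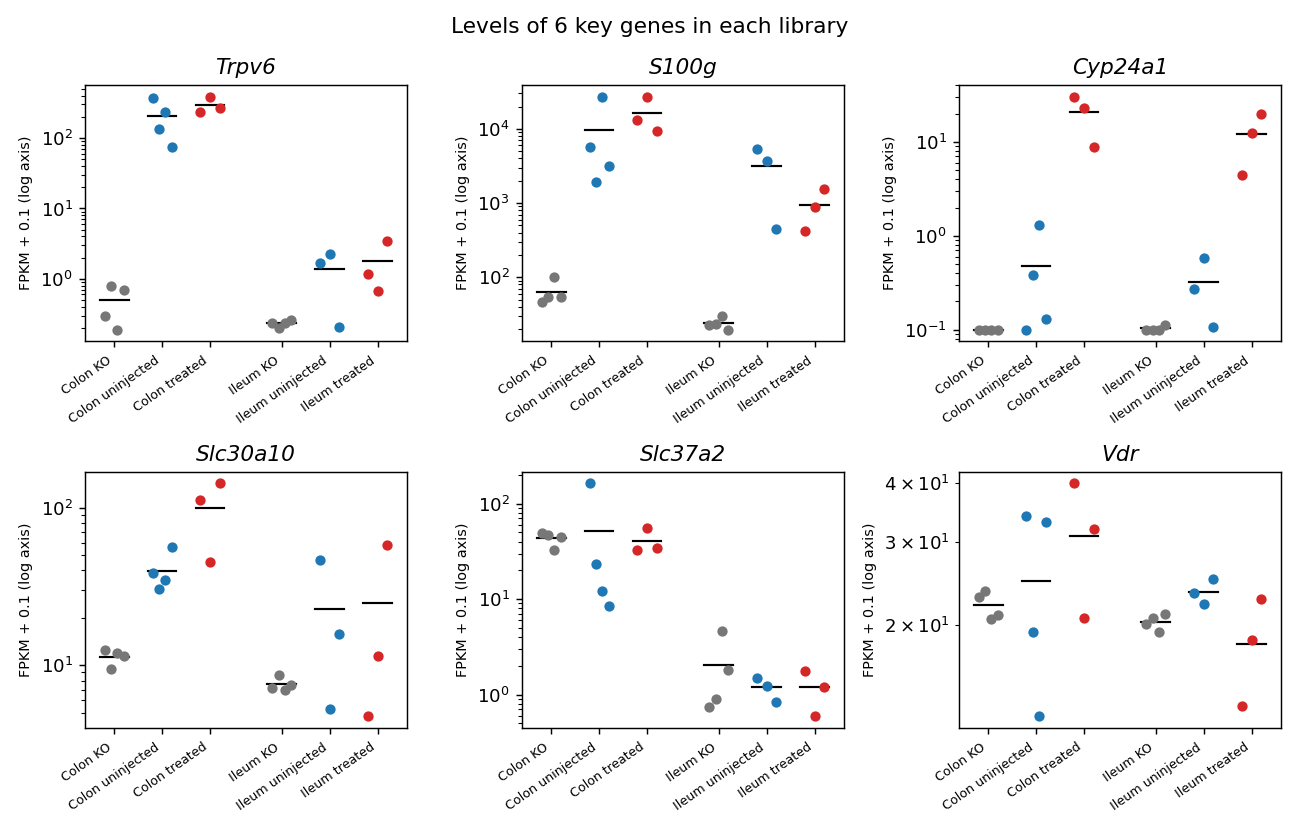
Levels of 6 genes in each library, as FPKM + 0.1 on a log axis, by tissue and group; each point is a library and each bar the group mean. KO and uninjected values come from the table that holds both, and treated values from the table shared with KO, whose scales differ slightly. Trpv6 lies between 75.3 and 388 FPKM in the uninjected and treated colon libraries and at most at 3.35 FPKM in the ileum, and Cyp24a1 is highest in the treated libraries of both tissues.

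In the colon, Trpv6 and S100g, 2 of 9 calcium transport genes tested, were far higher in the uninjected transgenic mice than in KO mice. Trpv6, the apical calcium channel of the epithelium (6:41570620-41586404), rose 202-fold, from 0.393 ± 0.295 to 205 ± 132 FPKM (SD, n = 4 each; log2 difference 7.66, SE 0.472, adjusted p = 0.000384, limma). Its KO levels lie near the added 0.5, and the log2 difference ran from 6.47 to 8.96 over the alternatives. S100g, the cytosolic calcium-binding protein calbindin-D9k (X:159399924-159402531), rose 91.6-fold, from 63.1 ± 24.5 to 9515 ± 11930 FPKM (log2 6.52, SE 0.712, adjusted p = 0.0129). Colon uninjected 3 carried that mean at 27300 FPKM, and without it the log2 difference was 5.75, the lowest of a range up to 7.02 with 1 library left out. Slc30a10, a manganese transporter (1:187278727-187292641), rose 3.35-fold (11.3 ± 1.30 to 39.8 ± 11.1 FPKM, adjusted p = 0.0275), and Slc34a2, the intestinal sodium-phosphate cotransporter (5:53429321-53462903), rose 4.18-fold (4.04 ± 0.757 to 18.4 ± 2.25 FPKM, adjusted p = 0.00832). In all 8 libraries of each of these genes the groups did not overlap.

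Of 12437 genes tested, 10 passed, 7 higher and 3 lower in uninjected mice (6 and 5 with quantile normalization). Also risen were Selenbp2, a selenium-binding protein (8.75-fold, 5.70 ± 1.60 to 52.6 ± 8.50 FPKM) and the unannotated 5033404E19Rik (5.69-fold, adjusted p = 0.04996). Ang3, of the angiogenin ribonuclease family, fell by 2.52 on the log2 scale, and Anxa13, an annexin of the intestinal epithelium, fell by 1.70 (40.4 ± 4.51 to 12.3 ± 2.61 FPKM). Snora74a, a small nucleolar RNA that overlaps a longer host gene, was listed at 0 in the 4 uninjected libraries and at 2.23 ± 0.792 FPKM in KO. Selenbp2 and Ang3 belong to families with closely similar copies, between which reads may be shared. Slc37a2, a sugar-phosphate exchanger, did not pass (log2 -0.77, SE 0.77, adjusted p = 0.748), with 163 FPKM in Colon uninjected 1 and 8.30 to 23.0 in the other uninjected libraries. Without Colon uninjected 1 its log2 difference was -1.66. Cyp24a1, the 24-hydroxylase that degrades 1,25D3, lay under the level filter, at 0 in the 4 KO libraries and at 0, 0.284, 1.2 and 0.0283 FPKM in the uninjected libraries. Trpv5, the calcium channel next to Trpv6, was listed at 0 in KO and at 0.0194 to 0.365 FPKM in uninjected colon (exact two-sided permutation p = 0.0286, the smallest possible with 4 against 4).

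Among the gene lists, 3 of the 4 genes tested from the protocol's qPCR panel rose and 1 did not pass, with 3 also when adjusted over the list alone. That list held its call with an estimated correlation (camera adjusted p = 3.71e-08 at the preset correlation, adjusted p = 0.0264 with an estimated correlation). The submitters picked that panel for their own measurements, so it is not independent evidence of direction. Of 9 calcium transport genes 2 rose, Trpv6 and S100g, and 7 did not pass, with the same count adjusted over the list alone (camera adjusted p = 0.017, but adjusted p = 0.268 with an estimated correlation). By fry the list was called upward (adjusted p = 0.00511), with Trpv6 and S100g as its only members past the test. Atp2b1, the basolateral calcium pump, stood at 76.0 ± 40.8 against 44.2 ± 3.65 FPKM and did not pass (log2 0.62, SE 0.356, adjusted p = 0.721). Of 4 phosphate transport genes Slc34a2 rose and 3 did not pass, among them the phosphate exporter Xpr1 (log2 -0.74, adjusted p = 0.721).

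Of 17 tight junction genes none passed, including the claudins Cldn2 (log2 -1.47, SE 0.376) and Cldn8 (log2 -1.22, SE 0.453), both at adjusted p = 0.721 (camera adjusted p = 0.0294 downward, and adjusted p = 0.815 with an estimated correlation). Limma passed 0 of the 16 Paneth and antimicrobial genes, over all genes or adjusted over the list alone. Ang4 lay at 241 ± 174 against 2345 ± 787 FPKM in KO (unadjusted p = 0.00316, limma) and the lectins Reg3g and Reg3b at log2 1.63 and 1.93 (unadjusted p = 0.0074 and 0.015). With 1 library left out, the log2 difference of Ang4 ran from -4.68 to -2.85. The metal-binding metallothioneins Mt1 and Mt2 had log2 differences of 1.18 and 1.35, and the lymphocyte genes Coro1a and Cd79a of 1.25 and 1.15, all at adjusted p = 0.721. Pancreatic acinar transcripts stood out in single libraries, with a median over 12 acinar genes of 2260 FPKM in Colon KO 2 and 5870 FPKM in Colon uninjected 3, against at most 32.2 FPKM in the other 6 libraries. The slope of the values on GC content was 0.86 log2 units per 10% in Colon uninjected 1.

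Fitted by limma, 572 genes had an unadjusted p under 0.05, and 337 genes (2.71%) had groups that did not overlap, where chance gives 2.86%. Leaving out 1 library moved the count between 2 (without Colon KO 1) and 68 (without Colon uninjected 4), with 3 without Colon KO 2, Colon KO 4 or Colon uninjected 2. Trpv6 and Selenbp2 passed in each of the 8 leave-outs. S100g was lost without Colon KO 1, 2 or 4 (adjusted p up to 0.0779), and Slc34a2 without Colon KO 1 or Colon uninjected 2. Anxa13 was lost without any KO library or Colon uninjected 2, and Ang3 and 5033404E19Rik without any KO library or Colon uninjected 1 or 2. Snora74a was lost without Colon KO 2, Colon KO 3, Colon uninjected 1 or Colon uninjected 2 and fell under the level filter without Colon KO 1 or Colon KO 4, and Slc30a10 was kept only without Colon uninjected 4. Over 13 other settings of the fit, Trpv6 kept its call in 13, S100g and Selenbp2 in 12, Slc34a2 in 11 and Anxa13 in 10. Slc30a10 kept it in 7 and lost it with quantile normalization, 3 groups in 1 fit, the sex covariate, the replicate block, voom and 2 libraries left out. The call of 5033404E19Rik was kept in 4 and lost with both other pseudocounts, no filter, no intensity trend, the sex covariate, the replicate block, the GC and length trend removed, voom and 2 libraries left out. Ang3 kept its call in 6 of 12 settings where it was tested and Snora74a in 6 of 11. With the labelled sex as a covariate Trpv6 alone passed. The KO mice were all labelled male. That fit therefore took the group difference from Colon uninjected 4 alone, the only male-labelled uninjected library, set against KO. It is a weak check of the other calls. Colon uninjected 3, labelled female, held the Y-linked Ddx3y at 12.2 FPKM.

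In treated against uninjected transgenic colon, limma called 0 of 12567 genes, with 143 at an unadjusted p under 0.05. Cyp24a1 (2:170308208-170322645) had the difference nearest to the threshold among the protocol's genes. It stood at 28.7, 21.6 and 8.43 FPKM in the 3 treated libraries against 0, 0.287, 1.2 and 0.0284 in the 4 uninjected libraries (log2 4.54, SE 0.562, adjusted p = 0.171), and passed when adjusted over its list alone, where it was 1 of 5 genes to rise. Slc30a10 lay at 94.8 ± 47.9 against 40.0 ± 11.2 FPKM (log2 1.11, adjusted p = 0.9995), Trpv6 at 278 ± 77.1 against 206 ± 133 FPKM and S100g at 15450 ± 8540 against 9549 ± 11940 FPKM, each with overlapping groups. The qPCR list was called upward at the preset correlation (camera adjusted p = 5.9e-06) and lost its call with the correlation estimated (adjusted p = 0.117 with an estimated correlation).

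Other groups leaned one way without a gene past the test. Of 7 endothelial genes each was higher in treated colon (camera adjusted p = 0.0443, and adjusted p = 0.785 with an estimated correlation). Of 20 leukocyte genes 15 were higher, led by the integrin Itgam (5.08 ± 2.82 against 1.46 ± 0.665 FPKM, unadjusted p = 0.00845, limma), at the same camera adjusted p = 0.0443 and adjusted p = 0.922 with an estimated correlation. Cholesterol biosynthesis genes were lower in 16 of 19 (camera adjusted p = 1.07e-05, and adjusted p = 0.577 with an estimated correlation). The stromal genes Lum, Dcn and Pdgfra had log2 differences of 1.54, 1.07 and 1.11 (adjusted p = 0.9995), while their list of 16 smooth muscle and stroma genes had a median of -0.13 and no call (camera adjusted p = 0.876). Groups did not overlap for 172 genes (1.37%), where chance gives 5.71%. Fits on simulated libraries recovered 25.2% of 4-fold and 66.4% of 8-fold changes here, so that changes of this size could pass unseen. Without Colon uninjected 3 the count was 4 genes, Ccl2, Cyp24a1, Hp and Spp1, named here after their values were seen, and with the 3 colon groups in 1 fit it was 4, with Cyp24a1 among them.

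The widest set of changes in the colon separated treated transgenic mice from KO mice. Trpv6 rose 328-fold, from 0.418 ± 0.312 (n = 4) to 294 ± 82.8 FPKM (n = 3; log2 8.36, between 7.69 and 9.78 over the alternatives, SE 0.307, adjusted p = 3.01e-05, limma), and S100g rose 230-fold, from 67.2 ± 26.5 to 16340 ± 9119 FPKM (log2 7.84, SE 0.406, adjusted p = 0.000163). Cyp24a1 was listed at 0 in the 4 KO libraries and stood at 30.4, 23.0 and 8.84 FPKM in the treated libraries (adjusted p = 0.00114). Atp2b1 (10:98377786-98488777) rose 2.52-fold (47.0 ± 3.92 to 121 ± 24.3 FPKM, adjusted p = 0.0298), Slc34a2 5.02-fold (adjusted p = 0.0118) and Slc30a10 7.26-fold (11.97 ± 1.40 to 99.9 ± 50.0 FPKM, adjusted p = 0.0201). In total 37 of 12505 genes passed, 28 higher and 9 lower in treated mice (38 and 25 with each library's trend on GC content and length removed).

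Hp, the haemoglobin-binding protein haptoglobin, rose 16.1-fold (7.90 ± 4.35 to 124.7 ± 52.3 FPKM), the serum amyloid Saa3 12.5-fold (4.89 ± 1.71 to 66.2 ± 17.7), the monocyte chemokine Ccl2 10.3-fold (1.56 ± 0.254 to 21.3 ± 7.08) and 5033404E19Rik 18.5-fold (adjusted p = 0.000163). Spp1, osteopontin, rose from 0.692 ± 0.974 to 13.0 ± 3.43 FPKM. Abhd1 rose to between 19.0 and 36.3 FPKM, against 1.19 in Colon KO 3 and 0 in the other KO libraries. AI506816 rose to between 4.32 and 14.6, against at most 0.0419 in KO. The sizes of the last 3 rest on the added 0.5, with log2 differences from 3.17 to 5.90, 4.59 to 9.34 and 3.35 to 9.12 over the alternatives. The 9 falls were led by Retnlb, a resistin-like protein secreted by goblet cells (10.6-fold, 1934 ± 508 to 212 ± 126 FPKM, adjusted p = 0.0422; log2 -3.41, and -2.75 without Colon treated 1). Next came the small proline-rich protein Sprr2b, which fell by 2.77 on the log2 scale, the steroid dehydrogenase Hsd3b3 (6.50-fold, 155 ± 38.9 to 23.1 ± 4.10 FPKM), the deacetylase Aadac (4.17-fold) and a second such protein, Sprr2a1, which fell by 1.92. Anxa13 (3.28-fold), Ccrn4l (3.06-fold), D330028D13Rik (2.64-fold) and the calpain Capn9 (2.11-fold) were the others. The Sprr2 and Hsd3b genes lie in clusters of near-identical copies on chromosome 3, between which reads cannot be told apart with certainty.

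**Figure D2:**
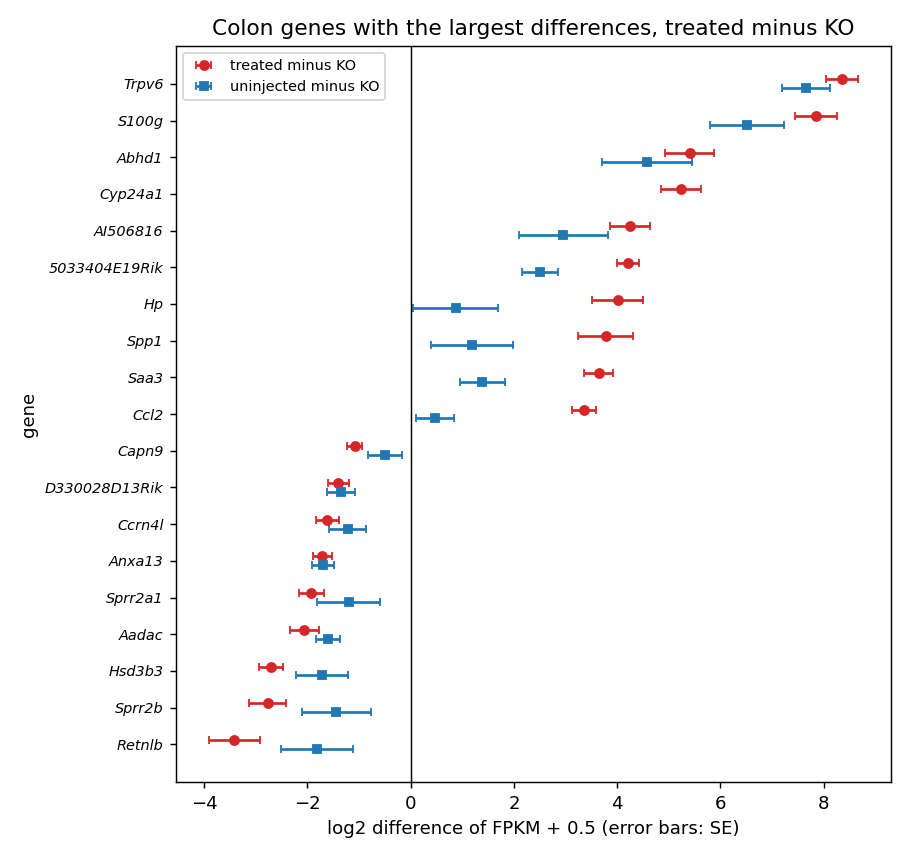
Log2 differences of FPKM + 0.5 in the colon for the genes with the largest differences between treated and KO mice; red points are treated minus KO (n = 3 and 4), blue squares uninjected minus KO (n = 4 each), error bars the SE. Trpv6 lies at 8.36 and 7.66 in the respective comparisons, while Ccl2 lies at 3.36 in treated minus KO and was not called in uninjected minus KO. Cyp24a1 was listed at 0 in KO, and Abhd1, AI506816 and Spp1 at or near 0 in some KO libraries, so the sizes of their points rest on the added 0.5.

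Of the 5 qPCR panel genes tested 4 rose, over all genes and adjusted over the list alone, and Slc37a2 did not pass (log2 -0.20, adjusted p = 0.858); the list held its call with an estimated correlation (camera adjusted p = 7.38e-13, and adjusted p = 0.0173 with an estimated correlation). Calcium transport genes rose in 3 of 9, Trpv6, S100g and Atp2b1, with 1 further gene down when adjusted over the list alone, the hormone Stc2 (log2 -0.69, adjusted p = 0.421 over all genes). The camera adjusted p = 0.0267 of the calcium transport list became an adjusted p = 0.614 with an estimated correlation, while fry called the list upward (adjusted p = 0.00643). Among 4 phosphate transporters Slc34a2 rose, and Slc20a1 lay at 34.3 ± 18.6 against 80.5 ± 32.6 FPKM (adjusted p = 0.504), counted as down adjusted over the list alone. The 10 goblet cell genes were all lower in treated mice and 0 passed over all genes, 2 when adjusted over the list alone, Fcgbp (log2 -1.38, SE 0.271) and Spink4 (log2 -1.61, SE 0.339). Muc2, the main colonic mucin, lay at 1027 ± 532 against 1730 ± 237 FPKM (camera adjusted p = 2.94e-05 for the list, and adjusted p = 0.58 with an estimated correlation).

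Of 16 Paneth and antimicrobial genes Retnlb fell and 15 did not pass, and adjusted over the list alone 3 rose, Reg3g and Reg3b among them (log2 2.13 and 3.12; Reg3b 2.32 without Colon treated 1 and 3.94 without Colon treated 2), and 2 fell, Ang4 with Retnlb (Ang4 197 ± 135 against 2494 ± 834 FPKM, adjusted p = 0.0543 over all genes). The list's camera adjusted p was 0.679. Leukocyte genes were higher in 17 of 19 with none past the test (camera adjusted p = 5.08e-05, and adjusted p = 0.614 with an estimated correlation), with Itgam at log2 1.35, Lyz2 at 0.64 and Laptm5 at 0.65. Of 16 smooth muscle and stroma genes 5 were lower and 1 higher adjusted over the list alone, the contractile genes Actg2, Cnn1 and Tagln lower by log2 values of -0.96, -0.84 and -0.92 (adjusted p = 0.122, 0.222 and 0.307), and 0 over all genes (camera adjusted p = 0.289). Colonocyte genes were lower in 16 of 20, including Scnn1a, the epithelial sodium channel subunit (log2 -0.87, adjusted p = 0.327), with 1 down adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.614 with an estimated correlation). Sgk1, a glucocorticoid and aldosterone target kinase, lay at 61.0 ± 9.56 against 125.4 ± 14.9 FPKM (adjusted p = 0.0683), Mt1 and Mt2 at log2 1.12 and 1.98 (adjusted p = 0.583 and 0.346), and the glial gene Gfap at log2 1.11 (adjusted p = 0.0683). Cholesterol biosynthesis genes were lower in 19 of 20, with Dhcr7 at log2 -0.64 (adjusted p = 0.292; camera adjusted p = 8.91e-05, and adjusted p = 0.614 with an estimated correlation). Acinar genes had a median of 874 FPKM in Colon treated 4 and 2260 FPKM in Colon KO 2, and at most 32.2 FPKM in the other 5 libraries.

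The limma fit gave 914 genes at an unadjusted p under 0.05, and 1006 genes (8.04%) had groups that did not overlap, where chance gives 5.71%. The count was 17 without Colon KO 1 or Colon KO 2, 19 without Colon KO 4, 24 without Colon KO 3 and 49 without Colon treated 4. Trpv6, S100g, Cyp24a1, Ccl2, Saa3, Abhd1, AI506816, Hsd3b3 and 5033404E19Rik passed in each of the 7 leave-outs. Slc30a10, Atp2b1 and Capn9 were lost without any KO library or Colon treated 1, Retnlb and Sprr2b without any KO library or Colon treated 4, and Sprr2a1 without Colon KO 1, 2 or 3 or Colon treated 2 or 4. Aadac and Ccrn4l were kept only without Colon treated 2, D330028D13Rik only without Colon treated 4 and Spp1 only without Colon KO 2. Slc34a2 was lost without Colon KO 1, Anxa13 without Colon KO 1 or 2, and Hp without Colon KO 2, Colon treated 1 or Colon treated 4. Over 11 other settings of the fit, Trpv6, S100g, Cyp24a1, Ccl2, Saa3, Abhd1, Slc34a2 and 5033404E19Rik kept their calls in 11. Hp and Hsd3b3 lost theirs with 3 groups in 1 fit, as did AI506816, and Slc30a10 and Anxa13 with the replicate block. Atp2b1 and Capn9 lost theirs with both of these, and Aadac with no filter and with the block. Retnlb, Sprr2a1, Ccrn4l, Sprr2b and D330028D13Rik lost theirs with no filter, 3 groups in 1 fit and the block, the last 2 also with voom. Spp1 kept its call in 5, and lost it with these 4, a pseudocount of 0.1 and a mean of at least 5 FPKM.

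Both colon comparisons with KO shared 7 upward calls, with Trpv6, S100g, Slc30a10, Slc34a2, Selenbp2 and 5033404E19Rik among them, and Anxa13 as 1 downward call, where independent lists of these sizes would share 0.014 and 0.0022. The comparisons share their KO libraries. Unchanged groups simulated against those libraries shared 0 genes, which says little, since no gene changes in them. With the KO libraries divided between the comparisons a mean of 1 upward call was shared. Log2 differences over 12282 genes had a covariance of 0.126 (r = 0.586 across genes, which are not independent replicates) against 0.039 (r = 0.203) in the simulation and 0.087 with divided KO libraries. The simulation drew each gene independently, without structure that real libraries may have in common, so it is not a full baseline.

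In the ileum, uninjected transgenic and KO mice differed past the threshold in 1 of 11827 genes. Cyp2c55, a cytochrome P450 (19:39081509-39117183), fell 8.54-fold, from 115 ± 14.3 (n = 4) to 13.7 ± 5.68 FPKM (n = 3; log2 -3.09, SE 0.304, adjusted p = 0.0328, limma). S100g lay at 5345, 3733 and 453 FPKM in the uninjected libraries and at 19.6 to 30.2 in KO, which did not pass (log2 6.44, SE 0.735, adjusted p = 0.0577), and counted as risen adjusted over the calcium list alone. Its log2 difference was 5.76 without Ileum uninjected 1, and 7.53 without Ileum uninjected 4, where it passed (adjusted p = 0.00012, and between 0.00012 and 0.294 over all alternatives). Trpv6, under the level filter here, stood at 0.133 ± 0.0247 FPKM in KO and at 1.59, 2.15 and 0.105 in uninjected libraries (exact two-sided permutation p = 0.114). Slc30a10 lay at 22.5 ± 21.6 against 7.48 ± 0.765 FPKM (adjusted p = 0.665) and Slc37a2 at 1.09 ± 0.334 against 1.94 ± 1.82 FPKM (adjusted p = 0.75). The log2 difference of Slc30a10 ran from 0.27 to 1.8 with 1 library left out. Cyp24a1 stood at 0.0117 FPKM in Ileum KO 4, 0 in the other KO libraries and 0.174, 0.482 and 0.00774 in uninjected libraries. Trpv5 was listed at 0 throughout the ileum.

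Xenobiotic metabolism was the list with the most low members. Of 26 tested genes Cyp2c55 fell and 25 did not pass, whereas adjusted over the list alone 7 fell, Cyp3a11 (8.15 ± 3.58 against 70.1 ± 27.7 FPKM, adjusted p = 0.202 over all genes), Cyp3a44 (log2 -2.43, adjusted p = 0.636) and Cyp2c65 (log2 -1.19, adjusted p = 0.665) among them. The list's camera adjusted p of 1.04e-06 became an adjusted p = 0.329 with an estimated correlation, and its fry adjusted p was 0.128. Reads of these clustered P450 genes may be shared between copies. Of 16 metal ion transport genes none passed, 2 rose adjusted over the list alone, the metallothioneins Mt1 (616 ± 242 against 191 ± 53.7 FPKM) and Mt2 (177 ± 4.64 against 47.1 ± 17.1 FPKM; adjusted p = 0.665 and 0.43 over all genes; camera adjusted p = 0.157). Among 10 glucocorticoid response genes 3 rose and 1, Sgk1 (log2 -1.76, adjusted p = 0.665), fell adjusted over the list alone, and 0 over all genes (camera adjusted p = 0.205). The acute-phase protein Saa1 lay at 832 ± 546 against 133 ± 52.8 FPKM (adjusted p = 0.665). Of 13 enteroendocrine genes 3 fell adjusted over the list alone and 0 over all genes, with Neurod1, Chgb and Tph1 at log2 -1.18, -2.13 and -1.47 (Chgb -2.98 without Ileum uninjected 4; camera adjusted p = 0.0128, and adjusted p = 0.707 with an estimated correlation). The stem cell genes Ascl2 and Lgr5 lay at log2 -1.25 and -1.04 and 10 of 12 members of their list were lower (camera adjusted p = 0.00547, and adjusted p = 0.722 with an estimated correlation). Cldn8 stood at 0.790 ± 0.876 against 4.04 ± 1.03 FPKM (adjusted p = 0.665). Ileum uninjected 3 stood apart from the other libraries, with a slope of 0.99 log2 units per 10% of GC content against -0.33 to -0.14 in KO.

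By limma 641 genes had an unadjusted p under 0.05, and 1018 (8.61%) had groups that did not overlap, where chance gives 5.71%. Cyp2c55 lost its call without any of the 4 KO libraries or Ileum uninjected 3 (0 genes each, adjusted p up to 0.241), and the count was 3 without Ileum uninjected 1 and 5 without Ileum uninjected 4. Of 11 other settings of the fit it kept its call in 6, and lost it with no filter, 3 groups in 1 fit, the replicate block, the GC and length trend removed and voom.

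In treated against uninjected transgenic ileum, limma called 0 of 11815 genes, with 97 at an unadjusted p under 0.05. Cyp24a1 was at 3.94, 11.3 and 18.3 FPKM in treated against 0.168, 0.466 and 0.00758 FPKM in uninjected libraries (log2 3.85, SE 0.583, adjusted p = 0.471), and rose adjusted over its list alone, as 1 of 5. S100g lay at 889 ± 530 against 3074 ± 2408 FPKM (n = 3 each, adjusted p = 1.0), Trpv6 at 1.55 ± 1.39 against 1.24 ± 1.02 FPKM and Slc30a10 at 22.9 ± 27.2 against 21.9 ± 20.9 FPKM, with overlapping groups. The log2 difference of S100g ran from -2.47 to -0.7 with 1 library left out. Of 8 bile acid genes 7 were lower and none passed. Fabp6, the ileal bile acid-binding protein, stood at 5681 ± 1943 against 21510 ± 12610 FPKM, Osta, a subunit of the bile acid exporter, at 492 ± 42.4 against 1140 ± 480, and the enterokine Fgf15 at 10.0 ± 14.9 against 23.8 ± 15.7 (camera adjusted p = 0.000112, and adjusted p = 0.354 with an estimated correlation). With 1 library left out, the log2 difference of Fgf15 ran from -3.49 to -1.41. The glucose transporter Slc2a2 and the tuft cell gene Alox5ap had log2 differences of 1.72 and 1.47 (adjusted p = 1.0). Tuft cell genes were higher in 5 of 6 (camera adjusted p = 0.0035, and adjusted p = 0.354 with an estimated correlation), and the 7 endothelial genes were all higher (camera adjusted p = 0.000203, and adjusted p = 0.354 with an estimated correlation). Of 17 Paneth and antimicrobial genes 12 were higher and 0 passed by limma, adjusted over the list alone as well (camera adjusted p = 0.00026, and adjusted p = 0.354 with an estimated correlation). All 7 MHC class II genes were lower (camera adjusted p = 0.000913, and adjusted p = 0.354 with an estimated correlation). Ileum treated 1 and Ileum uninjected 3, 1 library of each group, had the steep GC slopes (0.98 and 0.99 log2 units per 10% GC, against -0.53 to 0.05 elsewhere in these groups). Groups did not overlap for 319 genes (2.7%) where chance gives 10%, and on simulated libraries 14.4% of 8-fold changes were recovered, so that most changes could pass unseen. No exact test of 3 against 3 goes below 0.1.

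Between treated transgenic and KO ileum 10 of 11974 genes passed, 7 higher and 3 lower in treated mice (5 and 5 with quantile normalization). S100g rose 33.3-fold, from 25.0 ± 4.71 (n = 4) to 956 ± 561 FPKM (n = 3; log2 5.06, SE 0.408, adjusted p = 0.00206, limma). Cyp24a1 rose from 0.00309 ± 0.00619 to 12.01 ± 7.61 FPKM (adjusted p = 0.0105). The protease inhibitors Serpina3n and Timp1 rose 11.4-fold and 5.99-fold, and Arg1, arginase, 6.96-fold (0.689 ± 0.107 to 8.12 ± 3.09 FPKM, log2 2.38 to 3.43 over the alternatives). The unannotated 5033404E19Rik lay at 37.5 ± 38.7 against 0.0658 ± 0.108 FPKM (log2 5.54, but 6.27 without Ileum treated 1 and 4.70 without Ileum treated 4), and AI506816 at 9.93 ± 2.63 against 0.0156 ± 0.0186 FPKM. The sizes of Cyp24a1 and these 2 rest on the added 0.5, with log2 differences from 3.49 to 10.05, 4.65 to 8.41 and 3.40 to 8.78 over the alternatives. Hsd3b3 fell from 16.9 ± 6.54 to 0.401 ± 0.236 FPKM (adjusted p = 0.00206), a size that also rests on the added 0.5 (log2 -5.48 to -3.62 over the alternatives). Falls were also seen for the muscle actin Acta1, 15.2-fold (115 ± 48.1 to 8.09 ± 6.87 FPKM, adjusted p = 0.0422) and Cyp2c55, 13.0-fold (121 ± 15.6 to 10.4 ± 8.20 FPKM, adjusted p = 0.0148). Acta1 lay at log2 -3.92, at -4.53 without Ileum treated 4 and at -3.7 with the replicate number as a block. Its adjusted p was 0.088 with the block and between 0.00244 and 0.329 over all alternatives. Trpv6 stood at 1.67 ± 1.48 against 0.139 ± 0.0266 FPKM, under the level filter (exact two-sided permutation p = 0.0286, the smallest possible with 3 against 4). Slc30a10 did not pass (4.65, 11.3 and 57.8 FPKM in treated against 7.21 to 8.92 in KO, adjusted p = 0.939), nor did Slc37a2 (log2 -0.47, adjusted p = 0.939).

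Of the 4 qPCR panel genes tested 2 rose, with 2 also adjusted over the list alone (camera adjusted p = 5.72e-06, and adjusted p = 0.289 with an estimated correlation). Of 8 calcium transport genes S100g rose and 7 did not pass; adjusted over the list alone the magnesium channel Trpm6 also fell (log2 -1.57, SE 0.386, adjusted p = 0.587 over all genes; camera adjusted p = 0.942). Xenobiotic metabolism was again low, with Cyp2c55 down among 25 genes and 9 down adjusted over the list alone, including the carboxylesterase Ces2a (270.7 ± 42.9 to 70.1 ± 23.8 FPKM, adjusted p = 0.0715 over all genes), Cyp3a44 (log2 -2.92, adjusted p = 0.108) and Cyp3a11 (log2 -2.77, adjusted p = 0.143). The list's camera adjusted p was 1.61e-13, its adjusted p = 0.114 with an estimated correlation, and its fry adjusted p 0.0386. Bile acid genes were lower in 7 of 8, 1 of them adjusted over the list alone, with Fabp6 at 6118 ± 2033 against 27600 ± 9619 FPKM and Fgf15 at log2 -1.85 (-1.06 without Ileum treated 2 and -3.14 without Ileum treated 4; adjusted p = 0.32 and 0.939; camera adjusted p = 0.000816, and adjusted p = 0.498 with an estimated correlation). Mt1 and Mt2 lay at log2 1.62 and 2.4 (adjusted p = 0.195 and 0.183) and counted as risen adjusted over their list alone, as did Asns and Chac1, targets of the amino acid and stress response (log2 1.44 and 1.64, adjusted p = 0.152 and 0.493), 2 of 15 genes in the unfolded protein list (camera adjusted p = 0.0666). The sugar transporters Slc2a5 and Slc5a1 had log2 differences of 1.41 and 0.86 (adjusted p = 0.493 and 0.939); of 19 absorptive enterocyte genes 14 were higher, 1 risen adjusted over the list alone (camera adjusted p = 0.0125, and adjusted p = 0.552 with an estimated correlation). The 12 acinar genes were all higher in treated ileum (median log2 1.97, camera adjusted p = 2.5e-08, and adjusted p = 0.498 with an estimated correlation), with medians of 29.7 FPKM in Ileum treated 4 and at most 3.45 in the other 6 libraries.

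The limma fit had 437 genes at an unadjusted p under 0.05 and 599 (5%) whose groups did not overlap, where chance gives 5.71%. Without any 1 KO library 3 or 4 genes passed, S100g, AI506816 and Hsd3b3 each time, and these 3 passed in each of the 7 leave-outs; Cyp24a1, 5033404E19Rik and Arg1 were lost without any KO library or Ileum treated 2, Serpina3n without any KO library or Ileum treated 1, Acta1 and Cyp2c55 were kept only without Ileum treated 4 and Timp1 only without Ileum KO 3. Of the other settings of the fit, 3 groups in 1 fit ended the calls of S100g, AI506816 and Hsd3b3. Serpina3n kept its call in 7 of 12 settings and lost it with a pseudocount of 0.1, no filter, quantile normalization, the GC and length trend removed and voom. Timp1 kept its call in 6 and lost it with a pseudocount of 0.1, no filter, quantile normalization, 3 groups in 1 fit, voom, and the trend removed with the block. Acta1 kept its call in 5, 5033404E19Rik in 8 and Cyp24a1 and Cyp2c55 in 10, and Arg1 in 9 of 11. With the replicate number as a block the camera calls at the preset correlation widened to tight junction (adjusted p = 0.0362), smooth muscle (0.035) and sex-linked genes (0.00628), none of which held with an estimated correlation.

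Trpv6 was the only gene called for a difference of response between the tissues. On simulated libraries this test recovered 33.2% of 4-fold changes for uninjected minus KO and 35.2% for treated minus KO, so other differences could pass unseen. Trpv6 was low in the ileum and in KO colon, where the added 0.5 shrinks differences, so the sizes given here rest on it. The log2 difference of Trpv6 between uninjected and KO mice was 7.66 in the colon and 1.24 in the ileum (ileum minus colon -6.42, SE 0.718, adjusted p = 0.00273, limma; -5.76 without Ileum uninjected 4), and between treated and KO mice 8.36 and 1.55 (ileum minus colon -6.81, SE 0.542, adjusted p = 7.58e-05). No other gene passed among 12364 and 12448 tested (147 and 462 at an unadjusted p under 0.05), and limma called 0 of 12437 for treated minus uninjected (28 at an unadjusted p under 0.05). S100g responded by 7.84 in colon and 5.06 in ileum between treated and KO mice, a difference that did not pass (-2.79, SE 0.61, adjusted p = 0.341), and by 6.52 and 6.44 between uninjected and KO mice (-0.08, adjusted p = 1). The treated minus KO differences of Cyp24a1 (-0.83, SE 0.619), Slc30a10 (-1.98, SE 0.845; -1.20 without Ileum treated 1 and -2.95 without Ileum treated 4), Slc37a2 (-0.27) and Vdr (-0.59) did not pass either (adjusted p from 0.977 to 0.981). Treated minus KO shared calls between the tissues for 5 rises, S100g, Cyp24a1, Timp1, AI506816 and 5033404E19Rik, and 1 fall, Hsd3b3, where independent lists would share 0.014 and 0.0023. The labels do not say whether both tissues came from the same animals, so the lists are not known to be independent.

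**Figure D3:**
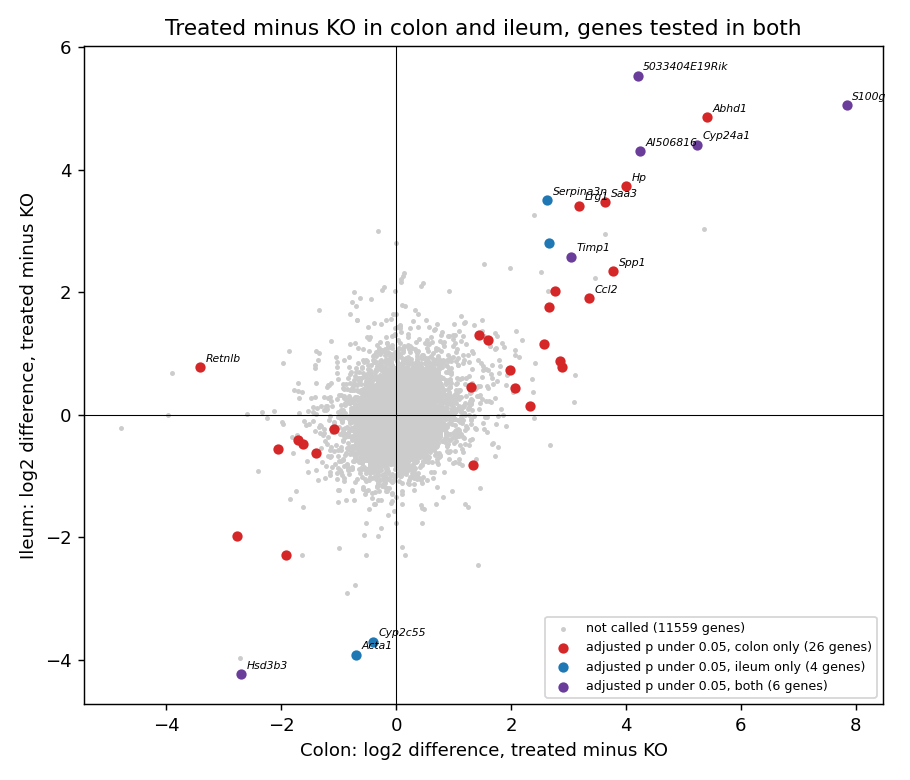
Log2 differences of treated minus KO in colon (horizontal) and ileum (vertical) for the 11595 genes tested in both; red points passed in colon only (26 genes), blue in ileum only (4), purple in both (6), and grey in neither (11559). S100g, Cyp24a1, AI506816 and 5033404E19Rik lie high on both axes and Hsd3b3 low on both; Trpv6, under the level filter in the ileum table, is not shown.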

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

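Of the tests in this part, those of the sex labels and of the trend on GC content were chosen only after the result was seen. The counts over other splits of the samples were fixed in advance. The exception is treated against KO ileum, where the splits used were narrowed after the correlations of same-numbered libraries were seen.

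Single libraries stood far from the other 3 of their group for 5 of 115 groups of 4 values tested (4.3%), where chance gives about 1 in 20 groups. A further 2 groups, those of Abhd1 and Cyp24a1 below, had 3 values at 0, so that any other value would stand apart there. S100g was at 99.4 FPKM in Colon KO 3 against 46 to 53.6 in the other KO libraries, and at 27300 FPKM in Colon uninjected 3 against 1930 to 5690. Slc37a2 was at 163 FPKM in Colon uninjected 1 against 8.3 to 23, and Xpr1 at 12.5 FPKM in Colon uninjected 4 against 5.06 to 6.31. Abhd1 was at 1.19 FPKM in Colon KO 3 and listed at 0 in the other KO libraries of the colon. Cyp24a1 was at 0.0117 FPKM in Ileum KO 4 and listed at 0 in the others, and 5033404E19Rik at 0.225 FPKM in Ileum KO 3 against 0 to 0.0377. The response of Trpv6 differed between the tissues by -6.42 (uninjected minus KO) and -6.81 (treated minus KO) on the log2 scale, by a test of the difference itself.

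Other splits of the same libraries into groups of the same sizes were counted. In the colon, 1 of 35 splits, the real one, gave as many genes for uninjected against KO (10 genes, at most 1 in the others). The same held for treated against KO (37 genes, at most 1 in the others). A share of 1 in 35 is the smallest possible here and was not adjusted over the comparisons. It argues against chance for these counts without excluding it. In uninjected against KO colon 2.71% of genes had groups that did not overlap, where chance gives 2.86%. For treated against KO in the ileum, the numbers were taken to pair the libraries. The real split was set against the splits that also part the 3 pairs, 8 with the real one. These are too few for a share under 0.05 (10 genes, at most 0 in the others). The rest of its 35 splits, which put both libraries of a pair in 1 group, gave at most 1 gene. Over all 35 splits, the count fixed in advance, 1 split, the real one, gave as many. Chance cannot be excluded for uninjected against KO in the ileum, where 2 of 35 splits gave as many (1 gene, at most 19, with Ileum KO 3, Ileum uninjected 1 and Ileum uninjected 3 set apart). For treated against uninjected colon the real split gave 0 genes, so all 35 of 35 gave as many. The split that set Colon uninjected 4, Colon treated 1 and Colon treated 4 apart gave 560, which points to a structure of the samples other than their groups. These were also the deepest libraries of the comparison, at an estimated 42.81, 31.99 and 26.16 M reads, against 10.68 to 23.7 M in the rest. Whether depth underlies this split was not tested. The 10 splits of treated and uninjected ileum are too few for a share under 0.05 (0 genes, at most 1). Among 100 regroupings for the difference between tissues, 11 gave as many genes for uninjected minus KO (1 gene, at most 4), 100 for treated minus uninjected (0 genes, at most 3333) and 7 for treated minus KO (1 gene, at most 10). Chance is thus not excluded for these counts of 1, and the regrouping with 3333 genes again points to a structure of the samples.

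Y-linked transcripts did not follow the sex labels in Colon uninjected 3, which is labelled female and held Ddx3y at 12.2, Eif2s3y at 11.6 and Kdm5d at 2.17 FPKM, against 11.7 to 20.3, 14.3 to 42.6 and 1.97 to 11.5 FPKM in male-labelled libraries of the colon, and its lowest ratio to the lowest of these was 0.811, which is consistent with a wrong sex label; Uty, at 0.845 FPKM, was not set against them since Colon treated 2 lists it at 0. A wrong sex label leaves open whether the group label is right, and S100g at 27300 FPKM in this library lies far above the KO libraries. In Ileum uninjected 3 and Ileum treated 1, Y-linked genes lay at -2.37 and -2.2 from the Ileum KO mean and at -0.94 and -0.46 once the trend on GC content and length was removed (SD of the KO libraries 0.59), so that GC and length bias may account for the low values, if the libraries are male. The labels call 2 of the 3 uninjected ileum samples female, yet 2 of the 3 libraries held Ddx3y (0.0344, 2.32 and 8.93 FPKM in Ileum uninjected 1, 3 and 4), so that in Ileum uninjected 3, whose column is not tied to a sample, the Y-linked transcripts rather than their low level can be what departs from the labels. Colon uninjected 1 held 0.0886 FPKM of Xist and listed Eif2s3y at 0, while Colon uninjected 2 held 5.92 FPKM of Xist. Ileum uninjected 1 likewise held 0.0798 FPKM of Xist and listed Eif2s3y at 0. Xist was at most at 0.101 FPKM in any ileum library, the female-labelled group included. No explanation was tested for these values.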

How the results depend on the processing

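Of the alternatives, removal of the GC and length trend, voom on recovered reads and the fits without 2 libraries that stood apart were chosen only after the data were seen. Over 133 named genes and comparisons, 2198 of 2481 values kept their direction and their side of the threshold, 246 lost the threshold, 21 gained it and 16 changed sign. Only genes past the threshold in the main fit could lose it, and many of those named were not past it. The share of values kept therefore does not measure how firm the calls were. How named calls held is given with each comparison above. Where a count or sign moved, the cause was not tested. Trpv6 passed in both colon comparisons with KO, and in both tissue differences with KO, under each alternative run. Few 2-fold changes were recovered on simulated libraries of any comparison, and what limits this was not tested.

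For uninjected against KO colon (10 genes, 3 of the 7 key genes), sex as a covariate left 1 gene, Trpv6, and 1 key gene. In that fit the group difference came from Colon uninjected 4 alone, the only male-labelled uninjected library of the colon. Leaving out 1 library gave 2 to 68 genes and 1 to 3 key genes, and without Colon uninjected 1 and 3 there were 8 genes, 5 of them shared. Quantile normalization gave 6 higher and 5 lower against 7 and 3. Xpr1 turned to 0.1 with sex as a covariate. In Colon uninjected 4 it stood at 12.5 FPKM, against 5.06 to 6.31 in the other uninjected libraries. Vdr turned to -0.06 with voom and to values from -0.12 to 0.34 with 1 library left out. For treated against uninjected colon (0 genes, 0 key genes), no filter gave 1 gene (Il7r), 3 groups in 1 fit gave 4 (Ccl2, Ccl7, Cyp24a1, Retnlg) with 1 key gene, and the trend removed gave 1 (Ccl2). Leaving out 1 library gave 0 to 4 genes and 0 to 1 key genes, and leaving out Colon uninjected 1 and 3 gave 0. Vdr turned to -0.23 with sex as a covariate, where Colon uninjected 4 alone again stands for the uninjected group. For treated against KO colon (37 genes), 3 groups in 1 fit gave 19 genes, 18 of them shared, and the trend removed gave 63, 33 of them shared (38 higher and 25 lower), with 17 to 49 when 1 library was left out. Genes named beside these small counts were chosen after their values were seen.

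For uninjected against KO ileum (1 gene, 0 key genes), a pseudocount of 0.1 gave 2 genes, adding 5033404E19Rik, and a mean of at least 5 FPKM gave 2, adding S100g, with 1 key gene. With 3 groups in 1 fit 1 key gene passed, and 0 genes passed with the trend removed or with voom. Leaving out 1 library gave 0 to 5 genes and 0 to 1 key genes. Slc37a2 lay between -0.65 and 0.07 with 1 library left out, and Vdr at -0.02 with voom. For treated against uninjected ileum (0 genes, 0 key genes), 3 groups in 1 fit gave 2 genes (Arg1, Cyp24a1) with 1 key gene, and leaving out 1 library, or Ileum uninjected 3 with Ileum treated 1, gave 0 each time. With 1 library left out Slc30a10 lay between -1.13 and 0.63, Trpv6 between -0.37 and 0.68 and Slc37a2 between -0.26 and 0.2, and Slc37a2 was at 0.02 with voom. For treated against KO ileum (10 genes, 2 key genes), a mean of at least 5 FPKM gave 1 key gene, 3 groups in 1 fit 4 genes with 1 key gene, and voom 4 genes. Leaving out 1 library gave 3 to 14 genes, 1 to 2 key genes, and Slc30a10 between -0.09 and 1.66. Quantile normalization gave 5 higher and 5 lower against 7 and 3.

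The number of genes whose effect differed between the tissues was 1 for uninjected minus KO, 2 with a pseudocount of 1 (adding Selenbp2) and 1 to 3 with 1 library left out. It was 0 to 1 with 1 library left out for treated minus uninjected (0 genes), the 1 being Gm4925 without Ileum uninjected 4. For treated minus KO (1 gene) it was 7 with no filter and 1 to 5 with 1 library left out. With 1 library left out, the tissue differences for uninjected minus KO ran from -0.76 to 1.02 for S100g, -0.13 to 0.33 for Vdr, -0.12 to 1.29 for Slc37a2 and -1.48 to 0.05 for Slc30a10; that of Trpv6 for treated minus uninjected ran from -1.01 to 0.03 and that of Slc37a2 for treated minus KO from -0.55 to 0.18. Gene lists called at the preset correlation numbered 8, 11, 9, 4, 13 and 7 in the 6 comparisons, colon first, and 1, 0, 1, 0, 0 and 0 with an estimated correlation.

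The replicate number as a block was tried in each comparison. It gave 3 genes for uninjected against KO colon (S100g, Selenbp2, Trpv6), 1 for treated against uninjected colon (Hp) and 18 for treated against KO colon, 16 of them shared. It gave 0 for uninjected against KO ileum, and for treated against uninjected ileum 34 (30 higher, 4 lower) with 1 key gene and Slc37a2 at 0.23, in a fit where the groups share 2 numbers. Same-numbered libraries correlated between -0.006 and 0.671, 0.069 and 0.392, -0.052 and 0.382, -0.188 and 0.591, and -0.396 and 0.656 in these 5 comparisons. They correlated best with their own number in 1 of 4, 2 of 3, 1 of 3, 2 of 3 and 1 of 2 pairs. The numbers were therefore not taken to pair all libraries there. Libraries numbered 4, however, deviated together in each (0.671, 0.392, 0.218, 0.591 and 0.656), best with their own number except at 0.218. What these libraries share is not given by the labels. In every group of both tissues, the library numbered 4 had the lowest slope of the values on GC content and the highest on transcript length. It was also the deepest of its group by estimated reads, except in treated colon. Whether this underlies their likeness was not tested. For treated against KO ileum the numbers were taken to pair the libraries, since each of the 3 pairs correlated over 0.1, though best with their own number in 2 of 3 pairs. There the block gave 11 genes, 9 of them shared, ended the call of Acta1 and of no other named gene, and with the trend removed as well 6 genes and 1 key gene. Across tissues the block left the counts at 1, 0 and 1. There, same-numbered libraries correlated between -0.143 and 0.627 in KO, 0.103 and 0.755 in uninjected and 0.032 and 0.598 in treated mice. They correlated best with their own number in 2 of 4, 2 of 3 and 2 of 3 pairs. The highest value of each group was that of the libraries numbered 4. Only in uninjected mice did each pair pass 0.1, the rule used for treated against KO ileum, and it was not applied across tissues. The labels do not say whether the tissues share animals. The sex covariate was not run in the ileum, since its columns are not tied to samples, and library weights were left out after they failed on simulated libraries.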

Other observations

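Of the tests in this part, those of the chromosome 3 window, of neutrophil markers, of the leukocyte share and of the trend on GC content were chosen only after the result was seen; the gene lists and overlaps were fixed in advance.

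Cell cycle genes were higher in treated than in KO colon in 22 of 24, with a median log2 difference of 0.471 and 0 past the test, over all genes or adjusted over the list alone. Ccna2, cyclin A2, stood at 32.8 ± 9.00 against 22.3 ± 4.12 FPKM (adjusted p = 0.6789, limma), and the list's camera adjusted p = 8.75e-05 became an adjusted p = 0.614 with an estimated correlation. Of 5 adipocyte genes 4 were higher, among them Fabp4, the fatty acid-binding protein of fat cells (241.5 ± 78.5 against 123.5 ± 39.5 FPKM, adjusted p = 0.4677; camera adjusted p = 0.0413, and adjusted p = 0.614 with an estimated correlation). Interferon response genes were higher in 15 of 20 and not called (camera adjusted p = 0.0903), with Isg15 at 160 ± 102 against 70.9 ± 24.9 FPKM. Between uninjected and KO colon, 6 of 7 endothelial genes were lower and 0 passed (camera adjusted p = 0.017, and adjusted p = 0.703 with an estimated correlation), with the receptor Kdr at 2.25 ± 0.453 against 3.65 ± 0.563 FPKM. In the same comparison the neuronal Uchl1 lay at 89.6 ± 60.4 against 23.8 ± 5.62 FPKM, and its list of 9 neuron and glia genes had 8 higher members (camera adjusted p = 0.0339, and adjusted p = 0.815 with an estimated correlation).

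Between treated and uninjected ileum, immediate early and heat shock genes were lower in 14 of 16 with 0 past the test (camera adjusted p = 0.000115, and adjusted p = 0.376 with an estimated correlation), led by the transcription factors Atf3 (18.0 ± 5.15 against 36.7 ± 12.6 FPKM) and Egr1 (4.02 ± 0.310 against 9.81 ± 4.58 FPKM). Cholesterol biosynthesis genes were lower in 18 of 19 (camera adjusted p = 0.000211, and adjusted p = 0.354 with an estimated correlation), and stem and progenitor genes higher in 10 of 12 (camera adjusted p = 0.000432, and adjusted p = 0.354 with an estimated correlation), with Ascl2 at 4.48 ± 2.88 against 2.15 ± 1.51 FPKM. These groups hold Ileum treated 1 and Ileum uninjected 3, whose slopes on GC content were 0.98 and 0.99 log2 units per 10%. The uninjected and the treated ileum, set against the same KO libraries, shared Cyp2c55 as a fall where independent lists would share 0.00026. Their log2 differences had a covariance of 0.149 (r = 0.669 across genes, which are not independent replicates), against 0.042 (r = 0.185) for simulated unchanged groups and 0.107 with divided KO libraries. As in the colon, the simulated genes were drawn independently, so this is not a full baseline.

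Genes that differed most from KO gathered in 1 window of chromosome 3 (90 to 100 Mb), picked as the highest of 274 to 276 windows, with 10, 12, 9 and 10 of the 200 leading genes of the 4 comparisons with KO (uninjected and treated colon, then uninjected and treated ileum, which share KO libraries within a tissue), where the highest window of 1000 random draws had a 95th percentile of 7. Removal of the GC and length trend left 10, 11, 6 and 9 window genes, and counting related neighbouring genes once left 7, 10, 8 and 8 families, so that each falls to the percentile or below in 1 comparison and either may account for part of the window. A genomic difference on chromosome 3 between the KO and transgenic animals may also account for it, and this cannot be told apart from regulation with these data. Of its 9 leading genes from uninjected against KO colon that were tested in the ileum, 8 kept their sign in treated against KO ileum (88.9%), but so did 78.5% of 163 leading genes elsewhere. Treated against uninjected mice, which would share such a difference, held 5 window genes in the colon and 3 in the ileum among their leading genes, where a window fixed beforehand has a 95th percentile of 4, so that the colon count lies above it and the ileum count below.

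The 12 genes Hp, Saa3, Ccl2, Ccl7, Lrg1, Retnlg, Timp1, Socs3, Tyrobp, Ifi204, Ifitm6 and Spp1 were picked by eye, as linked to inflammation, from those past the test in treated against KO colon, so their median log2 difference of 2.91 (quartiles 2.04 and 3.43) is set by that choice; their enrichment was not tested, and the leukocyte and interferon lists fixed in advance had no call with an estimated correlation (adjusted p = 0.614 and 0.751). The trend on GC content is argued against as the whole cause of these rises by a median of 2.71 once it was removed, with 9 of the 12 still past the test. The 19 leukocyte genes had a median of 0.53 (quartiles 0.3 and 0.75), and 17 of them were higher. Among them Lyz2 stood at 178 against 114 FPKM and Itgam at 5.35 against 1.66. Since the 12 genes were picked from those past the test, the gap between the sets is partly set by that choice. A larger share of leukocytes was thus neither shown nor excluded. Neutrophils may contribute and cannot be told apart from induction within the tissue, since 4 neutrophil markers listed after seeing the result had a median of 1.94 (quartiles 0.99 and 3.29), with S100a8 at 55.7 against 0.382 FPKM (log2 5.35, adjusted p = 0.0567, limma) but Cxcr2 at 0.13. Medians of the 12 genes in treated against uninjected colon (2.21) and, over 10 genes, in uninjected against KO colon (0.67) share libraries with the choice and so test nothing. In treated against KO ileum all 12 were higher (median 1.96, 1 past the test), but so were 77.7% of 103 other leading colon rises and 10 of 11 other called ones, and the labels do not say whether the tissues share animals, so that this does not test the group either, and effects of the treatment, the transgene or age, which partly coincides with group, stay open as untested.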
